A study of Mus musculus with 12 samples.

How the data were processed

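Peripheral blood mononuclear cells of APP/PS1 mice, collected on a density gradient, were measured by droplet single-cell RNA sequencing with 3′ version 3.1 chemistry in 12 libraries. The groups, per the labels, were 2-month controls (YTg), 12-month controls (OTg) and 12-month recipients of bone marrow from 2-month donors (YTg_BMCs), with 4 libraries each. The authors deposited, for each library, raw UMI counts per gene and cell barcode with no normalization, and, as other deposited values, the barcodes and the gene identifiers. Cell Ranger made the counts on mm10; the processing notes give version 2.1.1 and the file headers version 4.0.0. The gene table held 27998 genes and no constant genes of immunoglobulins or T cell receptors, so these were not analysed here. Each library held 4000 to 5252 barcodes and 22094689 to 38175440 UMIs, with a median of 3856 to 6968 UMIs per barcode. At most 0.246% of barcodes were shared between a pair of libraries. A check for mixed-up samples on sex-linked genes found 0 libraries unlike the others.

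Cells with fewer than 200 genes (344 of 53029 barcodes) or with over 10% mitochondrial UMIs (1099) were removed, which left 51586. Scrublet as run in scanpy 1.11.5, with an expected doublet rate of 0.05 and an automatic threshold per library, marked 1277 cells (2.48%) as doublets, and 50309 cells were kept. In OTg replicate 2 the automatic threshold marked 1 cell. A rule on markers that had been planned for this case would have marked 88.9% of that library and 74.8% of all cells and was not used; an alternative with the median threshold of the other libraries, 0.238, marked 92 cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were taken, and 30 principal components with 15 neighbours were clustered with leidenalg 0.10.2 at resolution 1.0. The 31 clusters were named by marker genes fixed beforehand; 5 clusters with 681 cells stayed unnamed and were left out of the classes. No batch correction was applied. Class sums used B cells (689 to 2284 per library), CD4 T cells (250 to 643), CD8 T cells (540 to 1134), NK cells (74 to 483), monocytes (196 to 1333) and neutrophils (20 to 110), with at least 20 cells required per class and library. Dendritic cells, basophils, plasma cells, platelets and erythroid cells were not compared.

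Counts were summed per class and library and tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM, filterByExpr, all 3 groups in one fit) under R 4.3.3, with Benjamini-Hochberg adjustment over the tested genes of each class and comparison and a threshold of 0.05. The comparisons were OTg with YTg, recipients with OTg and recipients with YTg. Levels are UMIs of a gene relative to all UMIs of the class in the library (CPM), means with SD over 4 libraries, and fold changes are on the log2 scale with their standard error (SE). Shares of leukocytes, without platelets and erythroid cells, were compared by a two-sided exact permutation test over 70 splits, adjusted over 18 tests; the smallest p it can give is 0.0286. Gene lists were fixed beforehand, 33 in number, of which 31 had the 5 members needed for a test in a class, and were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of each class and comparison. The position of recipients used genes called between 2 YTg and 2 OTg libraries and was scored in the other 4, over 36 such choices of which those with 20 or more genes were used, with exact permutation tests adjusted over 10 tests. Groups of 4 libraries do not overlap by chance in 2.86% of genes. Of the called genes of OTg and YTg, 125 of 129 in CD4 T cells and 227 of 239 in CD8 T cells had groups apart, as did 110 of 121 in CD8 T cells of recipients and YTg. As genes were called on these same libraries, most were bound to have groups apart, so these counts give no further support.

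Genes were named by a rule. For each class and comparison, among called genes with groups apart and a mean of at least 50 CPM in the higher group, the 3 largest rises and the 3 largest falls were taken, leaving out gene models, ribosomal, mitochondrial, haemoglobin, antigen receptor and sex-linked genes. To these were added the 8 genes called in the same direction in most classes, up to 4 called members of each list called by camera, and Apoe, Trem2, Cd36 and Cdkn1a in monocytes, Tlr2, Il1b, S100a8 and S100a9 in neutrophils, Ccr7 in CD4 T cells, Cdkn2a in CD8 T cells and Ccl5 in NK cells. The rule gave 82 genes in 134 results; a gene outside it is said to have been picked after its value was seen. The comparisons, tests, lists, rule and most alternatives were chosen before the data were examined. Coordinates are those of GRCm38 in GENCODE vM21.

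The alternatives tried were RLE normalization, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, only the compared groups in a fit, doublets kept, a stricter cell filter, resolutions 0.5 and 2.0, sums thinned to the smallest class total, each library left out in turn, other denominators and an edgeR test for shares, other gene thresholds and the signed median for the position, and camera with an estimated correlation and fry for lists. Further alternatives were added after the data were seen: cells with 3 or more of 10 B cell markers removed, a CD4 T cell and a monocyte cluster drawn mainly from a single library removed, clusters of few UMIs removed, monocyte subsets, the other doublet threshold, the block in a fit of YTg and recipients, and the position without genes at least 5 times higher in another class. The test was run on simulated data with 200 changed genes per class, all above a minimum mean level. It recovered 34% (neutrophils) to 99% (CD8 T cells) of 2-fold changes and 7% to 79% of 1.5-fold changes in the same classes. A position set to 0.5 was recovered as 0.518 in CD4 and 0.505 in CD8 T cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.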

Results

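Peripheral blood mononuclear cells of APP/PS1 mice, a transgenic model of cerebral amyloid deposition, were profiled by droplet 3′ single-cell RNA sequencing in 12 libraries, 4 in each of 3 groups. The young controls (YTg) were 2 months old and the old controls (OTg) were 12 months old. The recipients (YTg_BMCs) were irradiated with the head shielded at 9 months, received bone marrow of 2-month APP/PS1 donors and were sampled 3 months later. The libraries held 22094689 to 38175440 UMIs (unique molecular identifiers), with a median of 3856 to 6968 UMIs per barcode. After filtering, 50309 cells remained, and B cells, CD4 T cells, CD8 T cells, NK cells, monocytes and neutrophils were each compared between groups on counts summed per library. A gene is said to be called when its edgeR p, adjusted over all tested genes of the class and comparison, is under 0.05. The p-values measure the spread between these libraries, since the labels do not state that each library is a separate mouse.

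The blood of 12-month mice had lower mean shares of CD4 and CD8 T cells than that of 2-month mice in both 12-month groups, but no difference in share passed the adjusted test. CD4 T cells made up 15.5% ± 1.19 of leukocytes in YTg, 11.2% ± 2.73 in OTg and 9.94% ± 2.28 in recipients (SD, n = 4 each), and every YTg library lay above every library of both other groups. NK cells made up 8.77% ± 4.55 in YTg, 3.26% ± 1.69 in OTg and 5.79% ± 1.60 in recipients. B cells made up 30.4% ± 9.98, 36.8% ± 13.8 and 44.6% ± 8.96. CD8 T cells held 26.7% ± 2.37, 22.9% ± 2.08 and 20.1% ± 5.30. Monocytes held 14.5% ± 5.07, 21.004% ± 13.3 and 15.9% ± 6.42, and neutrophils 1.42% ± 0.625, 0.654% ± 0.191 and 1.23% ± 0.980. Both CD4 differences from YTg had the smallest p that the two-sided exact permutation test can give with 4 against 4 libraries, 0.0286. It was 0.171 after adjustment over 18 tests. None of the 18 differences passed the adjusted threshold of 0.05, and the edgeR test on cell counts called none either. In the permutation test most of the 18 differences would have to reach the smallest p before any could pass. Its outcome was thus nearly fixed and does not show that the shares were alike.

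**Figure D1:**
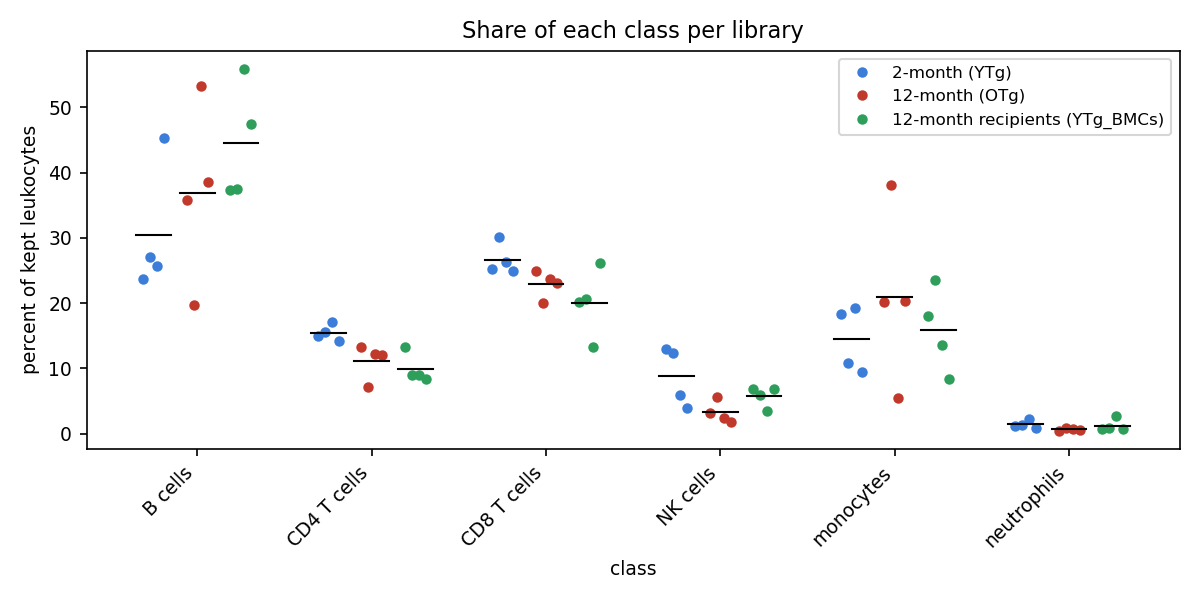
Share of each class among kept leukocytes in percent (vertical axis) for the 6 classes (horizontal axis). Points are libraries and lines are group means of 4 libraries; the CD4 T cell points of YTg lie above those of OTg and of the recipients.

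The comparison of OTg with YTg asks how blood leukocytes of these mice differ between 12 and 2 months of age. In CD4 T cells, genes of regulatory and memory T cells were higher at 12 months and genes of naive T cells were lower. Tnfrsf4 (OX40, a costimulatory receptor; ENSMUSG00000029075, chromosome 4, 156013843 to 156016612 on GRCm38) rose from 15.1 ± 1.41 CPM in YTg to 42.4 ± 6.79 CPM in OTg (SD, n = 4 each; log2 fold change 1.51 ± 0.16 SE, edgeR adjusted p = 5.79e-06). Ikzf2 (Helios, a transcription factor of regulatory T cells; ENSMUSG00000025997, chromosome 1, 69531214 to 69687245) rose from 45.03 ± 6.60 to 106 ± 29.3 CPM (1.25 ± 0.22). Capg, an actin-capping protein, rose from 43.2 ± 4.58 to 98.8 ± 19.5 CPM (1.18 ± 0.14). Tnfrsf18 (GITR) rose by a log2 fold change of 0.54 ± 0.13. All 10 tested members of the regulatory T list were higher, with a median of 0.83, and 5 of them were called over all genes and 6 adjusted over the list alone. This list rose by the set test (camera adjusted p = 9.03e-12; adjusted p = 0.106 with an estimated correlation). Of the 30 members of the memory and age-associated T list 28 were higher, 5 of them called and 17 adjusted over the list alone. The list rose (camera adjusted p = 4.71e-16; adjusted p = 0.122 with an estimated correlation). Among them, the annexin Anxa2 rose by 1.35 ± 0.29, the calcium-binding S100a11 by 1.16 ± 0.22, the chemokine receptor Cxcr3 by 0.95 ± 0.18 and the intermediate filament Vim by 0.73 ± 0.13 on the log2 scale. Most of these genes are far higher in other cell types, Anxa2 14.6 times and S100a11 14.3 times in neutrophils and Vim 7.97 times in dendritic cells. The highest other level of Cxcr3 was 1.48 times as high, in CD8 T cells. All 13 members of the naive T list were lower, 4 of them called and 7 adjusted over the list alone. The list fell (camera adjusted p = 3.44e-09; adjusted p = 0.122 with an estimated correlation). The called members were Dapl1 (-0.70 ± 0.16), the chromatin organizer Satb1 (-0.64 ± 0.13) and the transcription factors Lef1 (-0.53 ± 0.13) and Bach2 (-0.53 ± 0.12). The homing receptor Ccr7 was not called (log2 fold change -0.08 ± 0.17, adjusted p = 0.871).

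In all, 129 genes were called in CD4 T cells between OTg and YTg, 95 higher and 34 lower in OTg. Atp1b1, a sodium pump subunit, fell from 83.7 ± 7.05 to 46.4 ± 8.97 CPM. So did Pdlim4 (from 62.9 ± 6.48 to 35.2 ± 8.64 CPM) and Ly6c1 (from 167 ± 22.1 to 98.5 ± 25.6 CPM). The phosphatase Dusp1, an immediate early gene, rose by 0.64 ± 0.13, H2-Q6 of MHC class I by 0.64 ± 0.11, the lamin Lmna by 1.53 ± 0.26 and the protease inhibitor Cst7 by 1.09 ± 0.25 on the log2 scale. The makeup of the class differed as well. A cluster within it held 13.2% to 19.5% of the CD4 T cells of YTg libraries, 29.7% to 45.3% of those of OTg and 18.4% to 40.8% of those of recipients. Tested within this cluster and within the largest CD4 T cell cluster, 95 of 106 and 93 of 94 of the genes had the same direction, and at most 5 were called in either. As the genes were called on sums that hold these same cells, most were bound to share the direction. These counts thus give no further support for change within cells. Markers of other cells moved with the group. All 10 tested B cell markers had higher fitted values, with a median log2 fold change of 1.49, and Cd22 and Fcmr were called. H2-DMa of MHC class II rose by 0.74 ± 0.14. The myeloid gene Cd68 was 3.53 CPM in YTg and 12.5 CPM in OTg. Of the 129 genes, 46 were at least 5 times higher in another cell type. Without a CD4 T cell cluster that held 119 cells of OTg replicate 4 and at most 5 cells of any other library, 71 genes were called. Satb1, Lef1 and Bach2 of the naive T list, Anxa2, Cst7 and Fcmr lost their call there, and the other named genes tested there kept theirs. Their folds moved as well, from 1.35 to 0.97 for Anxa2, from -0.64 to -0.52 for Satb1 and from -0.53 to -0.44 for Lef1. With the class sums thinned to equal depth 62 genes were called, and with DESeq2 212. The count was 46 without YTg replicate 2, 63 without YTg replicate 4, 76 without OTg replicate 1 and 82 without OTg replicate 4. Of the 25 called genes chosen by the naming rule, 12 kept their call without any 1 of the 8 libraries: Tnfrsf4, Ikzf2, Capg, Vim, H2-Q6, Dusp1, H2-DMa, Lmna, Cd68, Csprs, Pdlim4 and Atp1b1.

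In CD8 T cells, Gzma was lower and Gzmm higher in OTg than in YTg. Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981), a serine protease of cytotoxic granules, fell from 1116 ± 138 CPM in YTg to 314 ± 83.2 CPM in OTg (log2 fold change -1.83 ± 0.29, edgeR adjusted p = 0.00809). Gzmm (ENSMUSG00000054206, chromosome 10, 79689020 to 79695261), another granzyme, rose from 46.5 ± 5.995 to 107 ± 27.5 CPM (1.19 ± 0.19, adjusted p = 0.00408). The largest rise of an abundant gene was that of Fcgrt (ENSMUSG00000003420, chromosome 7, 45092990 to 45103851), the neonatal Fc receptor, from 28.5 ± 4.68 to 72.8 ± 13.3 CPM (1.34 ± 0.14, adjusted p = 3.25e-06). Ctla2a, a protease inhibitor, rose from 329 ± 70.005 to 683 ± 148 CPM. Other falls were those of the receptor Klrg1 (-1.27 ± 0.26), the transcription factor Zeb2 (-1.01 ± 0.22) and the nuclear receptor Rora (-1.17 ± 0.22). Some of these genes are higher in other cell types, Gzma 20.1 times and Klrg1 6.13 times in NK cells, Zeb2 6.36 times in monocytes and Ctla2a 18.2 times in platelets. The mean share of NK cells was lower in OTg too. Platelets made up 1.37% to 4.62% of the kept cells of YTg libraries and 5.22% to 15.1% of those of OTg. Of the 12 NK cell markers in CD8 T cells, Gzma among them, 7 were lower in OTg, with a median log2 fold change of -0.11 (camera adjusted p = 0.876; adjusted p = 0.935 with an estimated correlation). Of the 17 members of the cytotoxic list 12 were lower, with 4 called falls, 2 called rises and 11 called adjusted over the list alone. The list fell (camera adjusted p = 0.00125; adjusted p = 0.848 with an estimated correlation). All 7 tested cycling markers were lower, with 3 called, Mki67 (-1.51 ± 0.29), Top2a (-1.23 ± 0.18) and Ube2c (-1.84 ± 0.37), and 4 adjusted over the list alone. The list fell (camera adjusted p = 2.99e-05; adjusted p = 0.271 with an estimated correlation). Their levels were low, with 5.81 CPM for Mki67 in YTg and 2.05 CPM in OTg. Of 82 ribosomal protein genes 79 were higher, with Rps12 called over all genes (0.37 ± 0.10) and no member called when adjusted over the list alone. The list rose (camera adjusted p = 1.76e-14; adjusted p = 0.848 with an estimated correlation).

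A total of 239 genes were called in CD8 T cells between OTg and YTg, 163 higher and 76 lower in OTg. The makeup of the class differed too, with clusters that held 20.7% ± 1.78 of CD8 T cells in YTg and 47.0% ± 6.45 in OTg, 45.5% ± 7.01 and 30.9% ± 4.46, and 33.8% ± 8.08 and 22.1% ± 4.07 (SD, n = 4 each). The kinase Mapk12, the protease Prss12 and Lmna rose from low levels, Prss12 from 5.96 ± 2.47 to 18.4 ± 1.10 CPM. Lmna is 20.3 times higher in platelets. In the interferon list Usp18 rose by 0.55 ± 0.14 and Ifi27l2a fell by 0.46 on the log2 scale, with 25 of 31 members lower (camera adjusted p = 0.0142; adjusted p = 0.865 with an estimated correlation). Cdkn2a, a senescence gene, was near the limit of detection, at 0.793 CPM in YTg and 0.848 CPM in OTg. Markers of B cells moved with the group here too, with a median log2 fold change of 0.84 over 10 markers, and H2-Eb1 of MHC class II rose by 0.89 ± 0.20 while Cd86 fell by 0.73. Of the 239 genes, 80 were at least 5 times higher in another cell type. Within the 3 clusters tested, 4 of 157, 43 of 201 and 62 of 173 of them were called. The count was 153 with the class sums thinned to equal depth. It was 151 without YTg replicate 2, 154 without YTg replicate 3, 133 without OTg replicate 1, 151 without OTg replicate 2 and 152 without OTg replicate 3. Of the 24 called genes chosen by the naming rule, 11 kept their call without any 1 of the 8 libraries: Fcgrt, Gzmm, Prss12, Mapk12, Csprs, Lmna, Cd22, Gzma, Mki67, Top2a and Ube2c.

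**Figure D2:**
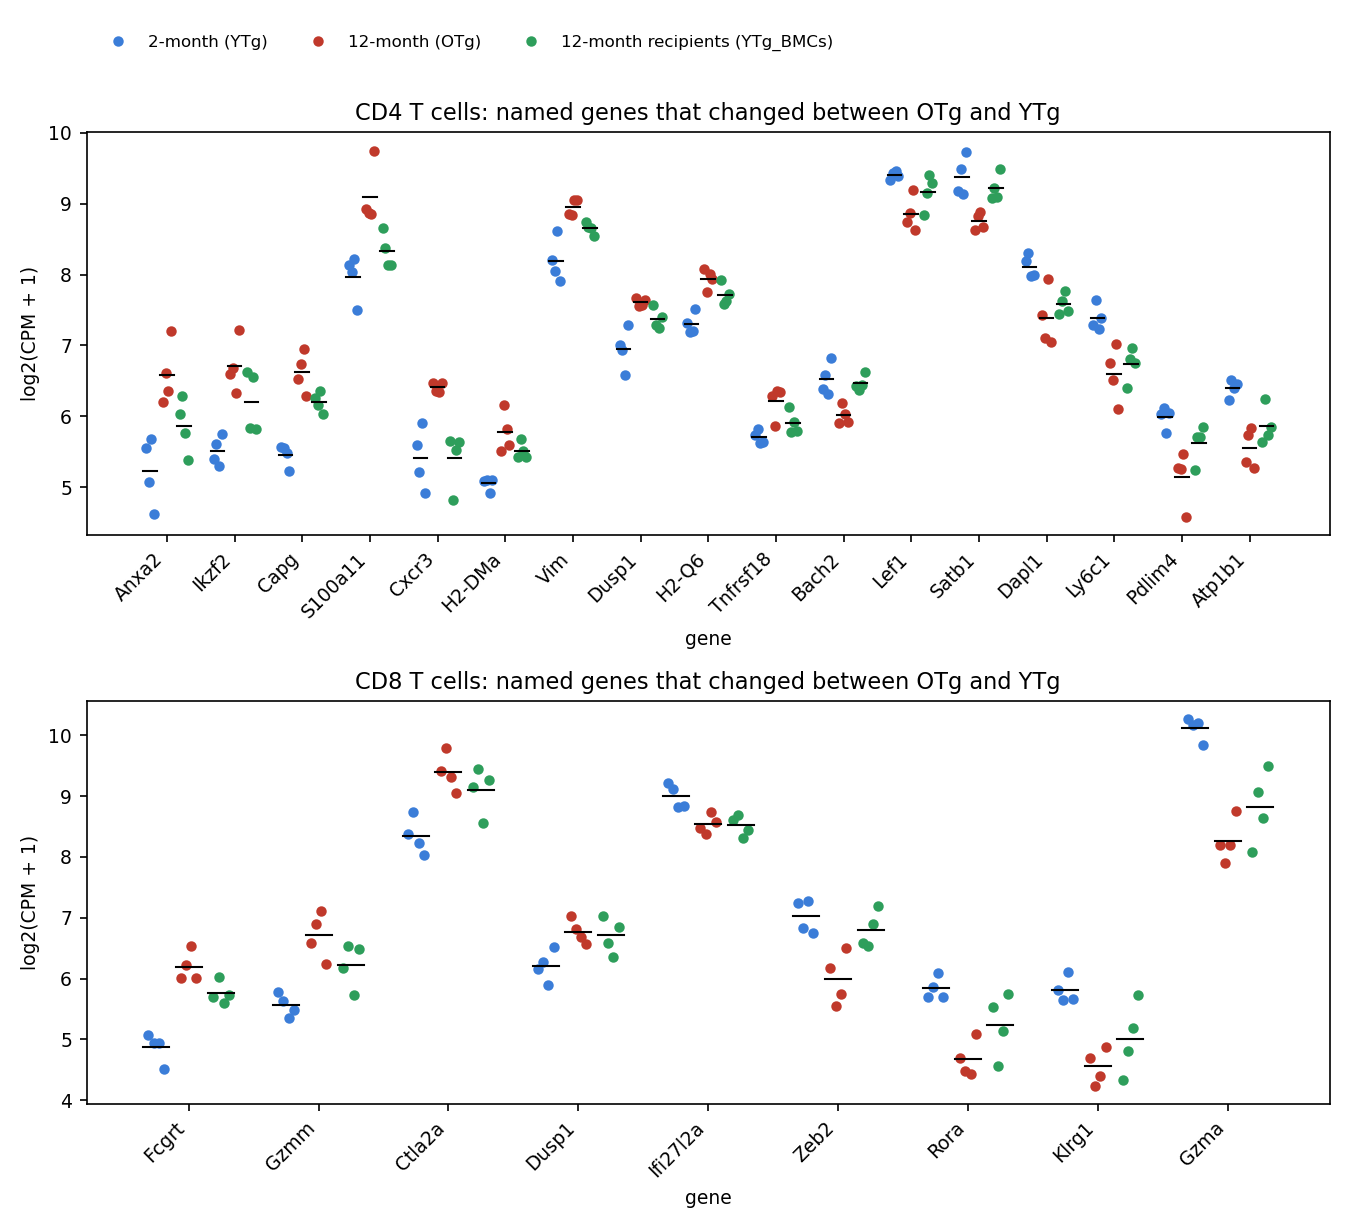
Level of named genes called between OTg and YTg in CD4 T cells (upper panel) and CD8 T cells (lower panel) that reached 50 CPM in the higher group, as log2 of CPM plus 1 (vertical axis) per gene (horizontal axis). Points are libraries and lines are group means of 4 libraries; the OTg and YTg points of each gene do not overlap.

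In B cells edgeR called 6 genes between OTg and YTg, while DESeq2, the replicate block and a fit with no filter on low counts each called more. Mapk12 (ENSMUSG00000022610, chromosome 15, 89130584 to 89140703), a p38 kinase, rose from 7.48 ± 1.33 to 17.2 ± 3.32 CPM (log2 fold change 1.18 ± 0.19, edgeR adjusted p = 0.00816), and Csprs from 9.97 ± 2.08 to 18.2 ± 2.43 CPM. Csprs rose in B cells, CD4 T cells and CD8 T cells, more classes than any other gene called between these groups, though its call in B cells ended without YTg replicates 1, 2 or 4 or OTg replicates 1, 3 or 4 (adjusted p up to 0.219), while its calls in CD4 and CD8 T cells held in every such fit. The other 4 genes lay outside the naming rule and were picked after their values were seen: the phospholipid transfer protein Pltp (1.19 ± 0.15), Snhg18 (1.26 ± 0.18) and the lipid-binding Stard10 (0.57 ± 0.11) rose, and the chromatin factor Cecr2 fell (-1.17 ± 0.17). The count in B cells was 12 without YTg replicate 3 and 10 without OTg replicate 4. In NK cells all 11 called genes rose. The cytokine Ltb rose from 46.5 ± 4.66 to 101 ± 30.4 CPM, the cathepsin Ctsz from 27.9 ± 0.573 to 57.7 ± 5.20 CPM and Ppp1r14b from 88.8 ± 13.4 to 143 ± 18.9 CPM. Genes of other lymphocytes rose beside them, among them Ebf1, Fcmr and Bank1 of B cells, H2-DMb2 of MHC class II and Cd3d of T cells. In all, 10 of the 11 genes were at least 5 times higher in another cell type. The B cell marker, T cell marker and MHC class II lists rose in NK cells also with an estimated correlation (camera adjusted p = 0.0137 for each). Adjusted over the list alone, 8 of 9, 4 of 7 and 9 of 9 members were called. The count in NK cells was 2 without OTg replicate 2, 4 without YTg replicate 1, 6 without OTg replicate 3 and 7 without OTg replicate 4. Without cells that held 3 or more B cell markers, 1 gene was called, and it was none of Ltb, Ctsz and Ppp1r14b. Of the 8 called genes chosen by the naming rule, Ltb alone kept its call without any 1 of the 8 libraries. All 8 lost their call with doublets kept. Bank1, Ebf1, Fcmr, H2-DMb2 and Ppp1r14b lost it with the other doublet threshold for OTg replicate 2. Ctsz was not called without OTg replicate 2, and Ppp1r14b lost its call in each of the 8 fits without 1 library (adjusted p up to 0.292).

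Monocytes and neutrophils differed little between the ages by the gene test. In monocytes the prion protein gene Prnp, picked after its value was seen, was the single called gene (1.74 CPM in YTg and 9.36 CPM in OTg, log2 fold change 2.35 ± 0.30), and it was not called without YTg replicate 1. Over all cells of a library, monocytes among them, Prnp measured 1.36 to 2.34 CPM in YTg and 3.52 to 5.96 CPM in OTg. In recipients it measured 2.90 to 4.59 CPM. Without OTg replicate 1, 3 genes were called in monocytes. Apoe, the apolipoprotein of the main Alzheimer risk locus, measured 2547 ± 266 CPM in YTg and 3342 ± 661 CPM in OTg (0.39 ± 0.14, edgeR adjusted p = 0.821). The lipid receptors Trem2 (-0.13 ± 0.20) and Cd36 (0.33 ± 0.43) and the cell cycle inhibitor Cdkn1a (-0.20 ± 0.34) were not called. Of 31 interferon response genes in monocytes 29 were lower in OTg, with a median of -0.31, and no member was called by edgeR adjusted over the list alone. The list fell (camera adjusted p = 2.52e-08; adjusted p = 0.821 with an estimated correlation). In neutrophils edgeR called 0 of 2537 genes, 107 had an unadjusted p under 0.05, DESeq2 called 2, and edgeR called 1 without OTg replicate 1. Their alarmins S100a8 (0.09 ± 0.35) and S100a9 (0.10 ± 0.28), the cytokine Il1b (-0.17 ± 0.26) and the receptor Tlr2 (-0.30 ± 0.40) were not called, nor was the chemokine Ccl5 in NK cells (0.08 ± 0.13). Neutrophils numbered 20 to 110 cells per library.

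The comparison of recipients with OTg asks how blood cells of mice that received young marrow differ from those of mice of the same age that did not. Which of the sampled cells came from the donors was not analysed here. The recipients alone were irradiated, so donor age, irradiation and transplantation cannot be told apart. In CD4 T cells 9 genes were called, 3 higher and 6 lower in recipients. Myo6 (ENSMUSG00000033577, chromosome 9, 80165031 to 80311729), an unconventional myosin motor, rose from 19.2 ± 3.47 CPM in OTg to 49.5 ± 11.2 CPM in recipients (log2 fold change 1.39 ± 0.17, edgeR adjusted p = 0.000263). The sialyltransferase St8sia6 rose from 44.4 ± 8.35 to 72.8 ± 4.66 CPM. Auts2 (ENSMUSG00000029673, chromosome 5, 131437333 to 132543344), a regulator of transcription in neurons, fell from 8.61 ± 0.843 to 1.78 ± 0.778 CPM in CD4 T cells (-2.24 ± 0.37, adjusted p = 0.0113). It also fell from 15.1 ± 1.99 to 4.66 ± 2.17 CPM in CD8 T cells (-1.72 ± 0.25, adjusted p = 0.00882). Other falls in CD4 T cells were those of Cst7 (-1.52 ± 0.28), the long noncoding RNA AW112010 (-0.75 ± 0.14) and the transcription factor Batf (-0.74 ± 0.13), as did the spindle gene Knstrn (-1.60 ± 0.32). AW112010 measured 338 CPM in YTg, 568 CPM in OTg and 337 CPM in recipients. St8sia6, AW112010 and Batf lost their call without the CD4 T cell cluster drawn mainly from OTg replicate 4. In the lists that moved with age, 12 of 13 naive T genes were higher in recipients than in OTg, with 3 called adjusted over the list alone (camera adjusted p = 1.18e-05; adjusted p = 0.303 with an estimated correlation). Of 30 memory and age-associated T genes 24 were lower, with 4 called adjusted over the list alone (camera adjusted p = 4.28e-07; adjusted p = 0.349 with an estimated correlation). These lists were looked at because they moved between OTg and YTg, and both comparisons share the OTg libraries, which alone can turn fold changes the other way. Across genes the fold changes of the 2 comparisons correlated by -0.699, in simulated data without any change by -0.520, and with the OTg libraries split between the comparisons by a mean of -0.271. In CD8 T cells 3 genes were called: Auts2, and, picked after their values were seen, Bmyc lower (-0.78 ± 0.14) and the cytokine signalling inhibitor Cish higher (0.97 ± 0.15). The count in CD4 T cells was 3 without recipient replicate 1, 2 without recipient replicate 2, recipient replicate 3 or OTg replicate 1, 1 without recipient replicate 4, 5 without OTg replicate 3 or 4, and 16 without OTg replicate 2. In CD8 T cells it was 0 without recipient replicate 1, OTg replicate 2 or OTg replicate 3, 1 without recipient replicate 3 or 4, and 8 without recipient replicate 2. Among the called genes of this comparison that the naming rule chose, only Myo6 in CD4 T cells kept its call without any 1 of the 8 libraries.

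In B cells 17 genes were called between recipients and OTg, 3 higher and 14 lower in recipients. The inhibitory Fc receptor Fcgr2b and the chemokine receptor Ccr6 fell in recipients. Fcgr2b fell from 116 ± 12.3 to 77.8 ± 3.10 CPM (log2 fold change -0.57 ± 0.11, edgeR adjusted p = 0.0331). Ccr6 fell from 70.7 ± 5.48 to 49.9 ± 3.42 CPM (-0.51 ± 0.10). Rap1gds1 rose from 41.7 ± 2.40 to 60.3 ± 5.07 CPM. Falls from lower levels were those of Zcwpw1 (-1.67 ± 0.24), Prss12 (-1.95 ± 0.35), Serpine2 (-1.98 ± 0.40) and Echdc3 (-1.73 ± 0.36), and DESeq2 gave none of these 4 an adjusted p. Of the 6 genes that differed with age in B cells, 5 were called in the opposite direction here, where both comparisons share the OTg libraries: Pltp (-1.13 ± 0.15), Snhg18 (-1.21 ± 0.17), Mapk12 (-1.25 ± 0.18), Stard10 (-0.68 ± 0.11) and Cecr2 (1.24 ± 0.17). Pltp measured 21.8 CPM in YTg, 49.1 CPM in OTg and 22.8 CPM in recipients, and Cecr2 29.1, 13.1 and 30.4 CPM. Of 19 age-associated B genes 15 were lower in recipients (camera adjusted p = 0.000547; adjusted p = 0.451 with an estimated correlation). Likewise, 6 of 7 immature and transitional B genes were higher (camera adjusted p = 0.00498; adjusted p = 0.274 with an estimated correlation). Each list had 3 members called adjusted over the list alone and none over all genes. The makeup of the class differed as well, with ranges that overlapped. A cluster held 5.04% to 7.88% of the B cells of recipient libraries and 0.871% to 5.48% of those of OTg. Another held 3.15% to 8.65% and 6.91% to 13.4%. What the makeup gave of these changes was not tested. The count was 8 without recipient replicate 1 or OTg replicate 3, 7 without recipient replicate 4 or OTg replicate 1, and 6 without recipient replicate 3. Of the 7 called genes chosen by the naming rule, none kept its call in every fit without 1 library. Pltp, Snhg18, Mapk12, Stard10 and Cecr2 lay outside the rule in this comparison and were not followed gene by gene through these fits.

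Genes of protein synthesis and respiration were lower in recipients than in OTg in several classes by camera, by small amounts. All 81 ribosomal protein genes were lower in B cells, with a median of -0.20 on the log2 scale (camera adjusted p = 2.00e-15; adjusted p = 0.458 with an estimated correlation). So were 81 of 82 in CD8 T cells (camera adjusted p = 2.03e-22; adjusted p = 0.908 with an estimated correlation). In NK cells all 80 were lower (camera adjusted p = 2.68e-20; adjusted p = 0.455 with an estimated correlation). Of the nuclear genes of oxidative phosphorylation, 73 of 76 were lower in B cells, with a median of -0.20 (camera adjusted p = 4.69e-12; adjusted p = 0.490 with an estimated correlation). In monocytes 71 of 75 were lower (camera adjusted p = 4.24e-09; adjusted p = 0.741 with an estimated correlation). No single gene of either list was called in these classes. NK cells had 1 called gene, the gene model Gm5547 (-1.24 ± 0.24), picked after its value was seen, with 859 genes at an unadjusted p under 0.05 and 0 called by DESeq2. The count was 16 without recipient replicate 2, 7 without OTg replicate 2, 3 without recipient replicate 4, 2 without OTg replicate 3, and 0 without recipient replicates 1 or 3 or OTg replicates 1 or 4. In monocytes edgeR called 0 genes, with 354 at an unadjusted p under 0.05 and 0 by DESeq2. In neutrophils edgeR called 0 genes, with 119 at an unadjusted p under 0.05 and 7 by DESeq2, or 4 by edgeR without OTg replicate 1 and 3 without recipient replicate 4. Apoe (-0.01 ± 0.14), Trem2 (-0.10 ± 0.20), Cd36 (0.00 ± 0.42) and Cdkn1a (0.07 ± 0.34) were not called in monocytes, nor were S100a8 (-0.61 ± 0.36), S100a9 (-0.58 ± 0.28), Il1b (0.15 ± 0.26) and Tlr2 (-0.10 ± 0.42) in neutrophils. Ccl5 in NK cells (-0.31 ± 0.13), Ccr7 in CD4 T cells (0.07 ± 0.17) and Cdkn2a in CD8 T cells (1.06 ± 0.52) were not called either.

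The comparison of recipients with YTg asks how far blood cells of mice that received young marrow differ from those of young mice. CD8 T cells differed in 121 genes, 88 higher and 33 lower in recipients. The makeup of the class differed as well, with a cluster that held 20.7% ± 1.78 of CD8 T cells in YTg and 39.4% ± 3.41 in recipients (SD, n = 4 each), and another with 45.5% ± 7.01 and 26.7% ± 7.52. With the profile of each cluster held fixed, a test chosen after the result was seen, the makeup gave 18.1% of the summed log2 change of the 121 genes (16.4% to 20.4% without each library in turn). Fcgrt rose from 28.5 ± 4.68 to 53.6 ± 7.26 CPM (log2 fold change 0.90 ± 0.14, edgeR adjusted p = 0.00106). The phosphatidate phosphatase Lpin1 (ENSMUSG00000020593, chromosome 12, 16535669 to 16610966) rose from 37.9 ± 5.29 to 75.5 ± 11.7 CPM (1.00 ± 0.16) and the transcription factor Klf6 from 449 ± 107 to 695 ± 91.0 CPM (0.63 ± 0.13). Dapl1 of naive T cells fell (-0.52 ± 0.13), as did the inflammasome adaptor Pycard (-0.65 ± 0.13), Eva1b (-0.67 ± 0.12), the interferon-induced Ifi27l2a (-0.49 ± 0.12) and Auts2 (-1.17 ± 0.26). All 7 cycling markers were lower, with Mki67 (-1.19 ± 0.28) and Ube2c (-2.74 ± 0.42) called and 3 adjusted over the list alone (camera adjusted p = 3.35e-05; adjusted p = 0.212 with an estimated correlation). Tppp (3.32 ± 0.57), Mapk12 (2.71 ± 0.61) and the titin gene Ttn (2.29 ± 0.53) rose from levels under 1 CPM. B cell markers moved with the group. All 10 had higher values and were called adjusted over the list alone, with Cd22, Ebf1, Bank1 and Cd79b called over all genes (camera adjusted p = 6.35e-16; adjusted p = 0.0727 with an estimated correlation). H2-Ab1 (1.02 ± 0.20), H2-Eb1, H2-DMb1 and H2-DMb2 of MHC class II rose with them, and 52 of the 121 genes were at least 5 times higher in another cell type. Without cells that held 3 or more B cell markers, 102 genes were called. Of the 21 called genes chosen by the naming rule, Ebf1, Bank1, Cd79b, H2-Ab1, H2-Eb1, H2-DMb2, Mapk12, Mki67, Ifi27l2a and Auts2 lost their call there.

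The changes of CD8 T cells in recipients followed those of age. Of the genes called in recipients, 71 were also called between OTg and YTg in the same direction, 57 higher and 14 lower, against 1.62 that independent calls would give. Both comparisons share the YTg libraries, and with these split between them 18.3 genes were shared on average. With the replicate number as a block, 225 genes were called in CD8 T cells and 271 with only YTg and recipients in the fit. Libraries of equal number in these 2 groups resembled each other, in that their deviations from the group mean correlated by 0.316 to 0.586 across genes in CD8 T cells. The count of 121 was 48 without YTg replicate 2, 58 without recipient replicate 1 and 74 without YTg replicate 1. Of the 21 called genes chosen by the naming rule, 7 kept their call without any 1 of the 8 libraries: Cd22, Ebf1, Eva1b, Fcgrt, Lpin1, Tppp and Ube2c. Of these, Ebf1 was not called without cells that held 3 or more B cell markers.

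In CD4 T cells 10 genes were called between recipients and YTg, 9 higher and 1 lower. Tnfrsf4 rose from 15.1 ± 1.41 to 33.1 ± 4.89 CPM (log2 fold change 1.13 ± 0.16, edgeR adjusted p = 0.000804) and Capg from 43.2 ± 4.58 to 72.8 ± 6.92 CPM (0.75 ± 0.14). In all, 9 of 10 regulatory T genes were higher, 4 of them called adjusted over the list alone (camera adjusted p = 2.61e-12; adjusted p = 0.113 with an estimated correlation). Auts2 was the single fall, from 9.12 ± 3.35 to 1.78 ± 0.778 CPM (-2.29 ± 0.36). Myo6, picked for this comparison after its value was seen, rose (1.23 ± 0.17). Both genes differed from the 2-month and from the 12-month controls in the same direction. Cd22 of B cells rose too (1.84 ± 0.36), and it was not called without cells that held 3 or more B cell markers. The count of 10 was 4 without YTg replicates 1, 2 or 4 and 3 without YTg replicate 3 or recipient replicate 1. Tnfrsf4 and Auts2 kept their call in every such fit. With the replicate number as a block the count was 22, or 133 with only YTg and recipients in the fit.

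B cells, NK cells, monocytes and neutrophils of recipients differed from YTg in few genes. By edgeR 0 genes were called in B cells (338 at an unadjusted p under 0.05, 0 by DESeq2). In NK cells edgeR called 0 too (385 at an unadjusted p under 0.05, 0 by DESeq2), as in neutrophils (123 at an unadjusted p under 0.05, 6 by DESeq2). In NK cells the count was 11 without recipient replicate 4 and 1 without YTg replicates 2 or 3 or recipient replicates 1 or 3, and in neutrophils it was 1 without YTg replicate 1. With the replicate number as a block the counts in B cells, NK cells and neutrophils were 0, 9 and 3, and with only YTg and recipients in the fit 24, 15 and 0. In monocytes the 3 called genes were the B cell genes Pax5 (2.46 ± 0.34) and Cr2 (3.08 ± 0.50) and, picked after its value was seen, Rasgrp3 (2.21 ± 0.35). No gene was called in monocytes without cells that held 3 or more B cell markers. Without recipient replicate 4 the count was 10, without recipient replicate 3 it was 1, and without any 1 of the other 6 libraries it was 0. With a block 17 genes were called in monocytes, or 9 with only YTg and recipients in the fit. The MHC class II list, whose genes B cells express too, was higher in NK cells of recipients, all 9 members and 8 adjusted over the list alone (camera adjusted p = 1.02e-16; adjusted p = 0.0478 with an estimated correlation). The 10 B cell markers rose in the same NK cells, from 106 ± 40.4 CPM in YTg to 235 ± 85.1 CPM in recipients, and cells with 3 or more of them from 0.825% to 6.85%. Of 504 tests of lists camera called 163, and 4 of these held with an estimated correlation, all in NK cells: 3 between OTg and YTg and that of MHC class II in recipients. The fry test, which asks whether the genes of a list move on balance in one direction, called 13. Immediate early genes were higher in CD4 T cells of recipients than of YTg, 19 of 22, with 2 called adjusted over the list alone (camera adjusted p = 2.35e-06; adjusted p = 0.258 with an estimated correlation). All 14 heat shock genes were lower, with no member called by edgeR adjusted over the list alone (camera adjusted p = 2.35e-06; adjusted p = 0.258 with an estimated correlation). Apoe (0.38 ± 0.14), Trem2 (-0.23 ± 0.20), Cd36 (0.33 ± 0.43) and Cdkn1a (-0.13 ± 0.34) in monocytes were not called. The same held for S100a8 (-0.52 ± 0.36), S100a9 (-0.48 ± 0.28), Il1b (-0.03 ± 0.26) and Tlr2 (-0.40 ± 0.38) in neutrophils, Ccl5 in NK cells (-0.23 ± 0.13), Ccr7 in CD4 T cells (-0.01 ± 0.17) and Cdkn2a in CD8 T cells (1.204 ± 0.52).

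The position of recipients between young and old was measured on age genes chosen in some YTg and OTg libraries and scored in the others, so that 0 is the YTg level and 1 the OTg level. CD8 T cells of recipients lay at 0.751 ± 0.146 (SD, n = 4), nearer to OTg than to YTg, on a median of 164 genes. Their libraries lay above all YTg libraries (two-sided exact permutation p = 0.0286, adjusted p = 0.143 over 10 tests), and against OTg the exact permutation p was 0.0571 (adjusted p = 0.190). CD4 T cells of recipients lay at 0.638 ± 0.315 (SD, n = 4) on a median of 50 genes, with exact permutation p = 0.0286 against YTg (adjusted p = 0.143) and p = 0.143 against OTg (adjusted p = 0.238). Without genes at least 5 times higher in another cell type, the position was 0.689 in CD8 T cells and 0.411 in CD4 T cells. In B cells, NK cells and monocytes the libraries of a group spread by more than the distance between the groups, and in neutrophils too few genes were called to score.

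**Figure D3:**
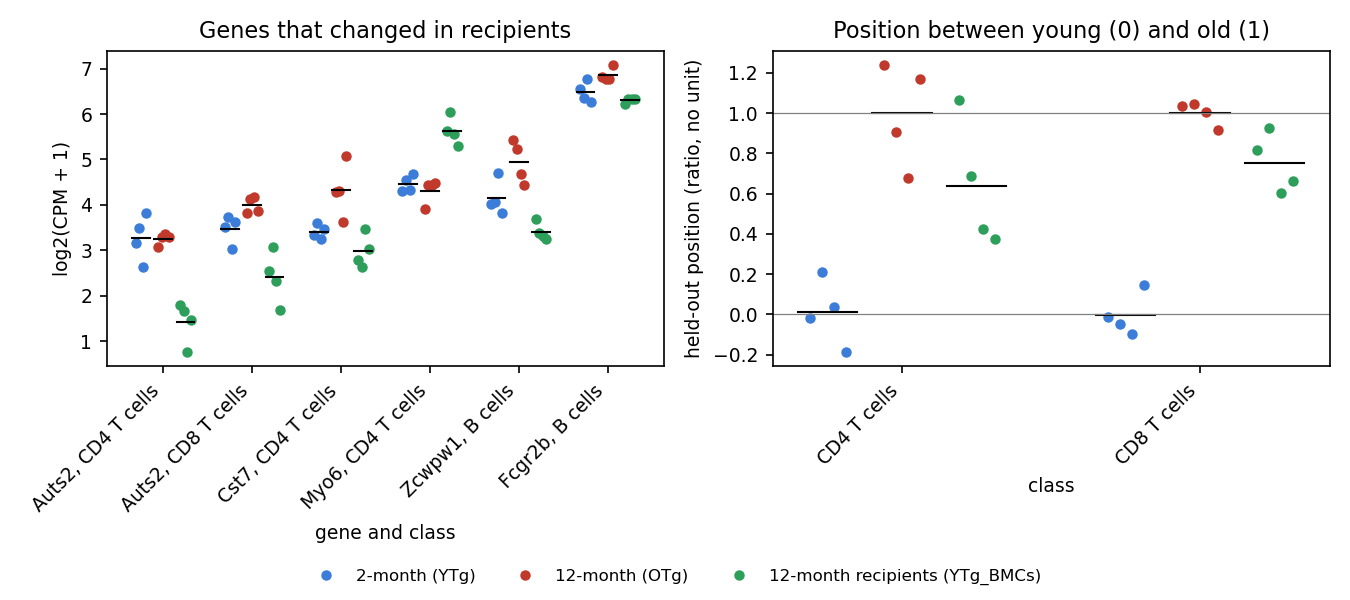
Left, levels of 6 genes and classes that were called in recipients, as log2 of CPM plus 1 (vertical axis) per gene and class (horizontal axis). Right, position of each library between the YTg level of 0 and the OTg level of 1 (vertical axis, no unit) in CD4 and CD8 T cells (horizontal axis). Points are libraries and lines are group means of 4 libraries; Auts2 in CD4 T cells lies lower in all 4 recipient libraries than in any other library.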

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

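The tests of RNA from other cell types in CD4 and CD8 T cells and of the OTg libraries shared between comparisons were chosen after the result was seen; the other tests here were chosen before it. A library was singled out when its gap to the nearest of the other 3 in its group took most of the group's range, a rule that chance meets in about 1 in 20 groups. Of 323 groups of 4 values 24 met it, where chance gives 16.2. Library measures met it in 5 of 15 groups, where chance gives 0.75, and shares in 3 of 18, where chance gives 0.9, while named gene levels met it in 16 of 288, where chance gives 14.4.

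Among library measures, OTg replicate 1 had a median of 6169.5 UMIs per kept cell and the other OTg libraries 5142 to 5291.5. In YTg replicate 4 the median mitochondrial share was 4.21% (3.01% to 3.18% in the others), 4591 cells were kept (3908 to 4022), 0.762% of cells lay in unnamed clusters (1.61% to 1.66%) and B cells made up 45.3% of leukocytes (23.8% to 27.1%). OTg replicate 2 had 5.21% of its cells in unnamed clusters (0.457% to 1.03%). CD4 T cells made up 13.3% of leukocytes in recipient replicate 1 (8.40% to 9.06%) and neutrophils 2.69% in recipient replicate 3 (0.674% to 0.848%). A cell population outside the compared classes stood out: a cluster led by the epithelial genes Tff1, Muc5ac and Krt8 held 4.40% of the kept cells of OTg replicate 2, 176 cells, and 0% to 0.326% of every other library.

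In CD4 T cells, single libraries stood apart for Cd68 (20.98 CPM in OTg replicate 4, 8.95 to 10.6 in the others), S100a11 (858 CPM in OTg replicate 4, 463 to 486), H2-DMa (29.3 CPM in YTg replicate 3, 33.1 to 33.2), Myo6 (13.97 CPM in OTg replicate 1, 20.6 to 21.3) and AW112010 (258 CPM in YTg replicate 4, 353 to 372). In CD8 T cells they did so for Csprs (2.67 CPM in OTg replicate 3, 3.85 to 4.06), H2-DMb2 (11.5 CPM in recipient replicate 3, 6.50 to 6.99), Bank1 (6.74 CPM in recipient replicate 4, 9.21 to 9.43), H2-Eb1 (25.2 CPM in YTg replicate 4, 17.1 to 18.2) and Klf6 (609 CPM in YTg replicate 4, 385 to 409, and 667 CPM in OTg replicate 1, 551 to 566). In B cells they did so for Mapk12 (5.49 CPM in YTg replicate 3, 8.01 to 8.39) and Fcgr2b (134 CPM in OTg replicate 4, 109 to 111, and 73.2 CPM in recipient replicate 1, 79.0 to 79.8). In NK cells they did so for Bank1 (27.8 CPM in OTg replicate 2, 20.4 to 20.7) and Ccl5 (16048 CPM in recipient replicate 1, 21361 to 22362).

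The age differences of T cells, 239 genes in CD8 and 129 in CD4 T cells, might come from cells within each class or from a changed makeup of the class. With the profile of each cluster held fixed, the makeup gave 29.2% of the summed log2 change of the called genes in CD8 T cells (27.8% to 30.3% without each library in turn). This argues against a changed makeup from these clusters as the whole cause there. In CD4 T cells the makeup gave 51.4% (44.7% to 56.1%), so that makeup and change within cells cannot be told apart. In both classes the clusters were drawn from the same genes, and a shift of subsets within a cluster would count as change within cells. RNA of other cell types would raise genes of those types, yet 159 of the 239 genes and 83 of the 129 were not 5 times higher in any other class. These counts pool rises with falls. In CD4 T cells all 46 genes that were 5 times higher elsewhere lay among the 95 rises, and in CD8 T cells 51 of 80 lay among the 163 rises. This argues against such RNA as the whole cause of the called genes. Its part in the rises stays open, also through genes less than 5 times higher elsewhere. Age, the named difference between these groups, stays open as an untested explanation. The labels do not say when the libraries were made. A batch of the OTg libraries therefore cannot be told apart from age here.

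B cell markers were higher in NK cells of OTg than of YTg, at 338 ± 93.0 and 106 ± 40.4 CPM (SD, n = 4) over 10 markers. Doublets of an NK cell and a B cell are a candidate source: 65.1% of the marker UMIs of OTg NK cells lay in cells with 3 or more markers, which made up 5.32% of them. Over the OTg libraries this share ran from 39.7% to 89.1%, and in YTg it was 17.3%; as the cells were chosen by these markers, it does not separate doublets from other cells that hold B cell RNA. Free B cell RNA stays open, since in NK cells with fewer than 3 markers the level was 1.36 times higher in OTg than in YTg, against 1.01 times in neutrophils, 1.26 in CD8 T cells, 1.44 in CD4 T cells, 1.48 in monocytes, 1.79 in erythroid cells and 2.08 in platelets. NK cells that themselves express B cell genes in 12-month mice were not tested.

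Of the 6 B cell genes called between OTg and YTg, 5 went the other way in recipients, a possible return to the young state. The makeup of B cells from its clusters gave 4.83% of the summed log2 change between OTg and YTg, which argues against it for that change. What the makeup gave of the change between recipients and OTg was not tested. Chance values of the OTg libraries, which both comparisons share, stay open. Libraries of equal number in YTg and recipients resembled each other in B cells (correlations of 0.429 to 0.534), so the OTg libraries were split between the comparisons with YTg and recipient libraries of different numbers in them. The fold changes across genes then correlated by a mean of -0.174 over 36 splits (-0.418 to 0.0722), 33 of them below 0. A batch of the OTg libraries that moves all cells alike stays open too. The genes called in B cells between recipients and OTg, 13 of them tested in other classes, showed there a median of 23.9% of their B cell change (95% bootstrap interval 4.62 to 36.4). Of the 5 genes, Pltp, Stard10 and Mapk12 were tested in other classes, with -9.07% to 122% of their B cell change. Donor age, irradiation and transplantation changed together in the recipients and stay open as untested explanations.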

How the results depend on the processing

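The tests with the replicate block in a fit of only YTg and recipients, without the CD4 T cell cluster of OTg replicate 4, without cells that held 3 or more B cell markers, with another doublet threshold for OTg replicate 2, without clusters of few UMIs, without the monocyte cluster of YTg replicate 3, on classical or nonclassical monocytes alone and of the position without genes of other cell types were chosen after the result was seen; the other alternatives were chosen before the data were examined. The 134 results on named genes gave 2768 values under the alternatives. Of these, 2232 kept their side of the threshold, 536 lost their call and 0 gained one. Among called genes 0 values changed sign. The 2232 include 70 values of genes that had not been called and that changed sign. Of the lost calls 331 were lost in fits without 1 library, from 17 without recipient replicate 2 to 38 without YTg replicate 2. The number of named results differs between libraries, and fewer libraries lower the power. The other 205 were lost most often with the class sums thinned to equal depth (33), without cells that held 3 or more B cell markers (27), at Leiden resolution 0.5 (26) and 2.0 (25), with doublets kept (23) and with the stricter cell filter (22), and seldom with DESeq2 (4), the replicate block (3) or RLE normalization (1). Thinning leaves fewer UMIs to test, and fewer named genes could be tested there; otherwise the cause was not tested. With RLE normalization all counts of called genes stayed within 1.5 times those with TMM.

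Counts of called genes that moved by more than 1.5 times are given for each setting. With DESeq2 they were between OTg and YTg 20 in B cells, 212 in CD4 T cells, 19 in NK cells, 9 in monocytes and 2 in neutrophils, between recipients and OTg 32 in B cells, 29 in CD4 T cells, 17 in CD8 T cells, 0 in NK cells and 7 in neutrophils, and between recipients and YTg 20 in CD4 T cells, 183 in CD8 T cells, 28 in monocytes and 6 in neutrophils. With no filter on low counts, where more genes are tested, they were between OTg and YTg 22 in B cells, 423 in CD4 T cells, 51 in NK cells, 4 in monocytes and 11 in neutrophils, between recipients and OTg 55 in B cells, 141 in CD4 T cells, 22 in CD8 T cells, 32 in NK cells and 19 in neutrophils, and between recipients and YTg 3 in B cells, 55 in CD4 T cells, 194 in CD8 T cells, 19 in NK cells, 6 in monocytes and 13 in neutrophils. With the replicate number as a block they were between OTg and YTg 22 in B cells, 198 in CD4 T cells, 20 in NK cells and 4 in monocytes, between recipients and OTg 34 in B cells, 22 in CD4 T cells, 2 in NK cells and 6 in neutrophils, and between recipients and YTg 22 in CD4 T cells, 225 in CD8 T cells, 9 in NK cells, 17 in monocytes and 3 in neutrophils. With this block and only YTg and recipients in the fit they were between recipients and YTg 24 in B cells, 133 in CD4 T cells, 271 in CD8 T cells, 15 in NK cells and 9 in monocytes. With only the compared groups in the fit they were between OTg and YTg 6 in monocytes, between recipients and OTg 27 in B cells, 6 in CD8 T cells, 2 in monocytes and 1 in neutrophils, and between recipients and YTg 25 in CD4 T cells, 3 in NK cells and 0 in monocytes. With thinned sums, which hold fewer UMIs, they were between OTg and YTg 62 in CD4 T cells, 153 in CD8 T cells, 7 in NK cells and 0 in monocytes, between recipients and OTg 7 in B cells, 4 in CD4 T cells and 0 in NK cells, and between recipients and YTg 2 in NK cells and 1 in monocytes. Apart from the number of genes tested, the depth and the pairing of libraries that these settings change by construction, the cause was not tested.

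Choices on cells moved fewer counts. With doublets kept the counts were between OTg and YTg 0 in NK cells and 3 in monocytes, between recipients and OTg 5 in CD4 T cells and 0 in NK cells, and between recipients and YTg 18 in CD4 T cells, 10 in NK cells and 12 in monocytes. With the stricter cell filter they were between recipients and OTg 1 in CD8 T cells and 2 in NK cells, and between recipients and YTg 5 in NK cells and 1 in monocytes. At resolution 0.5 they were between OTg and YTg 4 in monocytes, and between recipients and YTg 29 in CD4 T cells, 1 in NK cells and 1 in monocytes. At resolution 2.0 they were between OTg and YTg 5 in NK cells, between recipients and OTg 5 in CD8 T cells, and between recipients and YTg 1 in monocytes. With the other doublet threshold for OTg replicate 2 they were between OTg and YTg 3 in NK cells, and between recipients and YTg 2 in NK cells. Without cells that held 3 or more B cell markers they were between OTg and YTg 1 in NK cells, between recipients and OTg 7 in CD8 T cells, and between recipients and YTg 6 in CD4 T cells and 0 in monocytes. Without the CD4 T cell cluster of OTg replicate 4 the count was between OTg and YTg 71 in CD4 T cells. Without clusters of few UMIs the counts were between OTg and YTg 2 in monocytes, and between recipients and YTg 1 in monocytes. In classical monocytes alone the count was between OTg and YTg 4 in monocytes. The cause was not tested. Of 504 list tests camera called 163 with its preset correlation and 4 with an estimated correlation, fry called 13, and the replicate block left 159.

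Leaving out each library in turn gave the following ranges of called genes. Between OTg and YTg the counts ran from 4 to 12 in B cells, 46 to 152 in CD4 T cells, 133 to 289 in CD8 T cells, 2 to 15 in NK cells, 0 to 3 in monocytes and 0 to 1 in neutrophils. Between recipients and OTg the counts ran from 6 to 21 in B cells, 1 to 16 in CD4 T cells, 0 to 8 in CD8 T cells, 0 to 16 in NK cells, 0 to 0 in monocytes and 0 to 4 in neutrophils. Between recipients and YTg the counts ran from 0 to 0 in B cells, 3 to 12 in CD4 T cells, 48 to 154 in CD8 T cells, 0 to 11 in NK cells, 0 to 10 in monocytes and 0 to 1 in neutrophils. The libraries that moved a count by more than 1.5 times are named with the results, and fewer libraries lower the power of each such fit.

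Differences in mean share, in percentage points of leukocytes, ran as follows when each library was left out in turn. Between OTg and YTg they ran from 0.895 to 12.1 in B cells, -5.01 to -2.98 in CD4 T cells, -4.42 to -2.61 in CD8 T cells, -7.12 to -4.11 in NK cells, 0.817 to 11.7 in monocytes and -0.945 to -0.462 in neutrophils. Between recipients and OTg they ran from 2.00 to 13.2 in B cells, -2.56 to -0.536 in CD4 T cells, -4.89 to -0.574 in CD8 T cells, 2.04 to 3.32 in NK cells, -10.3 to 0.562 in monocytes and 0.0842 to 0.757 in neutrophils. Between recipients and YTg they ran from 10.3 to 19.1 in B cells, -6.68 to -5.02 in CD4 T cells, -8.64 to -4.32 in CD8 T cells, -4.60 to -1.58 in NK cells, -1.16 to 3.88 in monocytes and -0.677 to 0.111 in neutrophils. In all, 321 share values were computed under the alternatives and none passed the adjusted threshold. For the permutation tests among them this was nearly fixed by the smallest p they can give. The sign of 7 of them changed: for monocytes of recipients and OTg without OTg replicate 2, for monocytes of recipients and YTg at both other resolutions, without clusters of few UMIs, without YTg replicate 4 and without recipient replicate 2, and for neutrophils of recipients and YTg without YTg replicate 3. Without each recipient library in turn the position ran from 0.496 to 0.725 in CD4 T cells, 0.694 to 0.801 in CD8 T cells, -0.754 to -0.00387 in B cells, -1.61 to 2.28 in NK cells and 0.389 to 1.37 in monocytes. With genes chosen at an unadjusted p under 0.01 it was 0.494 in CD4 and 0.732 in CD8 T cells, with the signed median 0.624 and 0.735, and each stayed within the spread between libraries.

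On simulated data edgeR recovered 99% of 2-fold changes in CD8 T cells, 96% in B cells, 95% in monocytes, 94% in CD4 T cells, 83% in NK cells and 34% in neutrophils. For 1.5-fold changes it recovered 79%, 70%, 49%, 52%, 26% and 7% in the same order. False calls made up 1.37% (monocytes) to 6.82% (neutrophils) of the calls, and 6.41% in CD4 T cells. Changes were set only in genes above a minimum mean level, so recovery at lower levels was not measured. The classes differ in cells, depth and spread between libraries, and which of these sets the recovery was not tested. With the sums thinned to equal depth the count between OTg and YTg was 62 and not 129 in CD4 T cells and 153 and not 239 in CD8 T cells.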

Other observations

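The genes and tests of a single CD8 T cell cluster were chosen after the result was seen; the splits of libraries were chosen before it. The cluster was led by Ccl5, Gzmk and Klrc1 and held 131 to 456 cells per library. In it Bcl2, which protects lymphocytes from apoptosis, rose from 172 ± 43.3 CPM in YTg to 433 ± 67.4 CPM in OTg (log2 fold change 1.35 ± 0.14) and 465 ± 34.2 CPM in recipients (1.46 ± 0.14; SD, n = 4 each). The protease Prss12 (3.75 ± 0.42 in recipients), the chemokine Xcl1 (2.92 ± 0.68) and the transcription factor Klf6 (1.24 ± 0.18) rose in both groups against YTg, and Plac8 (-0.97 ± 0.16) and the inflammasome adaptor Pycard (-0.96 ± 0.12) fell in both. In recipients the immediate early genes Fos (1.503 ± 0.35) and Fosb (1.89 ± 0.42) and the interleukin receptor Il7r (1.22 ± 0.29) rose too, and the serpin Serpinb6b (-1.15 ± 0.19), Eva1b (-1.07 ± 0.15) and the chaperone Hspa8 (-0.71 ± 0.16) fell.

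Of 8002 genes tested in this cluster, 170 were called between OTg and YTg (111 higher, 59 lower; 161 by DESeq2, 259 with the replicate block) and 360 between recipients and YTg (201 higher, 159 lower; 283 by DESeq2, 498 with the block). The first count was 78 without OTg replicate 1, and the counts ran to 194 and 480 without YTg replicate 4; the second was 181 without recipient replicate 1. In both comparisons 91 genes were called, all in the same direction, 64 higher and 27 lower, against 2.79 and 1.17 for independent calls, and 18 to 28 were shared when the YTg libraries were split between the comparisons. Other splits of the libraries gave at most 14 genes where the first gave 170 and at most 51 where the second gave 360, so that the real split was the 1 of 35 with as many in each. The cluster was chosen after the result was seen and had the most called genes of the clusters tested in these comparisons. The share of 1 in 35, the smallest possible, was not adjusted for that choice, so chance is not excluded. Whether the changes in this cluster differ from those in other CD8 T cells was not tested.

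For each count of called genes the same test was run on all 35 splits of the 8 libraries. Between OTg and YTg the real split was the 1 with as many genes in B cells (6 genes, highest other 1), CD4 T cells (129, highest other 0), CD8 T cells (239, highest other 1) and NK cells (11, highest other 1). This argues against chance for these counts. In monocytes the same held for a count of 1 gene (highest other 0), which was not called without YTg replicate 1 and is too few to rest on. With 35 splits the smallest share is 1 in 35, and it was not adjusted over the counts tested, so that chance is not excluded for any count. In neutrophils, where edgeR called 0 genes (107 at an unadjusted p under 0.05, 2 by DESeq2), the highest other gave 1; a count of 0 is reached by all 35 splits whatever the data, so this says nothing on chance. Between recipients and OTg the splits argue against chance in CD4 T cells (9, highest other 4, 1 of 35 splits). They do not in B cells (17, highest other 29, 2 splits), CD8 T cells (3, highest other 33, 3 splits) and NK cells (1, highest other 20, 8 splits). By edgeR 0 genes were called in monocytes (354 at an unadjusted p under 0.05, 0 by DESeq2; highest other 22) and neutrophils (119 at an unadjusted p under 0.05, 7 by DESeq2; highest other 7), where all 35 splits reach 0 by construction and say nothing on chance. In B cells and CD8 T cells the split with most genes set replicates 1 and 2 of both groups against replicates 3 and 4, which points to a structure of the libraries. Pairs of equal number in these groups had correlations of -0.224 to 0.168 in B cells and -0.216 to 0.305 in CD8 T cells, so that a pairing by number is not shown.

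Between recipients and YTg the splits argue against chance in CD8 T cells (121, highest other 10, 1 of 35 splits). By this count they do not in CD4 T cells (10, highest other 11, 2 splits) and monocytes (3, highest other 85, 2 splits). By edgeR 0 genes were called in B cells (338 at an unadjusted p under 0.05, 0 by DESeq2; highest other 24), NK cells (385 at an unadjusted p under 0.05, 0 by DESeq2; highest other 16) and neutrophils (123 at an unadjusted p under 0.05, 6 by DESeq2; highest other 5), where the splits say nothing on chance for the same reason. In B cells, NK cells and monocytes the split with most genes, and in CD8 T cells the one with most after the real split, set replicates 1 and 3 of both groups against replicates 2 and 4, which points to a structure of the libraries by replicate number; libraries of equal number in these groups had like deviations. The real split parts all 4 pairs of equal number. Among the 8 splits that do so the highest other count was 1 in CD4 T cells, where the real one gave 10, and 0 in CD8 T cells and in monocytes, where the real ones gave 121 and 3. With 8 splits the smallest share is 1 in 8, too coarse to argue against chance. With the block and only these groups in the fit the counts were 133 in CD4 T cells, 271 in CD8 T cells, 24 in B cells, 15 in NK cells and 9 in monocytes.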
